A study of Mus musculus with 2 samples.

How the data were processed

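Total RNA from the midbrain of mouse embryos (strain B6NCrl, embryonic day 16.5) was sequenced in 2 libraries, each a biological replicate made from pooled embryos of mixed sex. Per the labels, 10 ng of RNA longer than 200 nucleotides entered each library with spike-in sequences. A gene table and a transcript table were used for each library. Per the deposited readme the reads were aligned to mouse genome mm10 and its transcriptome, and quantified against GENCODE release M4 with spike-in sequences. The aligner, the quantifier and their versions are not given in the sources used here; the column names are those RSEM writes.

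Per the file headers, the expected count of the deposited tables is the estimated number of reads per gene or transcript, with reads that fit several features divided among them and no normalization. Per the file headers, the deposited TPM values are transcript abundances corrected for effective length and scaled to the same total in each library, with spike-ins included in that total. Per the file headers, the deposited FPKM values are fragments scaled by effective length and by the number of reads of the library. Per the file headers, the isoform share of the deposited transcript tables is a percent of the TPM of its gene. Posterior mean counts, TPM and shares and credibility intervals of TPM, whose level is not stated, are further deposited columns.

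Each gene table has 69691 entries: 43346 Ensembl genes, 97 spike-in sequences (96 ERCC sequences with 10 at no count in either library, and phiX at 0) and 26248 entries named by a number only, with lengths of 61 to 259 bases, whose identity is not stated. The numbered entries held 12 expected counts in each library and were kept apart. Symbols, gene types and coordinates came from GENCODE M21, which is built on GRCm38, the same assembly as mm10, and were joined by the Ensembl identifier without version. The 884 identifiers without a match held 0.194% and 0.179% of expected counts. Lhfpl3, Snord3a and Sox2ot were not measured under these symbols, and Dlx6os1 stood on 2 identifiers. Transcript tables have 129984 entries, 103639 of them Ensembl transcripts, and a transcript is described only if its length is the same in both annotation releases.

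Depth was 31830355 expected counts in replicate 1 and 36576263 in replicate 2, and 73.2% and 72.9% of the genes with a count had one that was whole to within 0.005. Intervals and floors are at 95% and at 3 counts, and they cover counting error only, since reads without molecular identifiers are not independent molecules. A gene with 0 counts in 1 library was compared against the floor of 3 counts, scaled like the other counts, and for a gene with 1 to 3 counts in 1 library the ratio of scaled counts with nothing added is given with its interval.

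A gene was called detected at a TPM of at least 1 in both libraries. Shares of TPM leave out spike-ins, whereas TPM of single genes is as deposited. List levels are medians of TPM, ranked among 10000 random lists of protein-coding genes of the same size. Ratios between pools used expected counts with 0.5 added, scaled by TMM factors from edgeR 4.0.16 on rounded expected counts, for genes with a mean expected count of at least 50, and for list members at least 10. A list was compared if at least 4 members passed, against 10000 random lists matched in 20 bins of expression. The biological coefficient of variation came from the common dispersion of edgeR on rounded counts. Size factors from DESeq2 1.42.0, also on rounded expected counts, were an alternative scale. The correlation used log2(TPM + 1). Transcript shares used genes at 5 TPM or more in both libraries with at least 2 transcripts. Calculations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3.

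With 1 group and 2 libraries no test between conditions and no p-value can be had. The 34 gene lists, the ratios between genes, the thresholds and most of the other settings tried were fixed before the data were examined. The rule for named genes, fixed at the same time, took the 15 nuclear protein-coding genes of highest mean TPM, the 3 highest members of each list and any member below 1 TPM in both libraries, the genes of the ratios, the 8 genes per direction with the largest difference among those at 2-fold, and the genes of the transcript list. Some genes and ratios that these rules take are not described. Other named genes were chosen after their values were seen, among them En1, Aldoc, Aqp4 and Neurog2 in the results and the single genes in the closing part, such as Spp1 and Zic4. Further lists for tests between the pools, named there, were written down before their values were looked at, except that Cck and En1 had been seen.

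The 2-fold rule was tested on simulated data of 17788 genes with a coefficient of variation of 10%, which was recovered as 10.02%. Of 200 genes changed, all of those at log2 1.5 and 99% of those at 2 were recovered, with 3 calls among 14225 unchanged genes. The simulation gave every gene the same spread and divided no shared reads, so its rate of false calls does not carry over to the data. Of 200 random lists of 12 genes 2.5% fell outside the central range, and 98.5% did when shifted by log2 0.3. Of 100 random pairs of lists 7% fell outside, and 100% did when shifted by 0.5; a simulated trend of 0.2 per SD of GC content was removed to a slope of 0. Alternatives tried were other thresholds, units and pseudocounts, posterior means, DESeq2, spike-in and TPM scales, other count minimums, gene types and leaving out each library.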

Results

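Total RNA was sequenced from the midbrain of mouse embryos at embryonic day 16.5. The labels give 1 group of 2 biological replicates, each a pool of embryos of mixed sex, and the same donor identifier for both. The pool of replicate 2 held 37 embryos, and the number is not given for replicate 1. Expected counts summed to 31830355 in replicate 1 and 36576263 in replicate 2, and 23524 and 23769 genes had any count. At these depths 1 read on a gene of 1 kilobase corresponded to 0.0600 and 0.0515 TPM. Values written with ± are the mean and SD over the replicates (n = 2), in TPM unless another unit is named. With a single group no test between conditions exists, and every difference between the pools is a description of these 2 libraries.

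The first comparison asks which genes made up most of the RNA of the embryonic midbrain. Tuba1a, an alpha-tubulin of growing neurons, was the highest protein-coding gene of the nuclear genome at 16553 ± 243, and Stmn1, a regulator of microtubule turnover, reached 6851 ± 533. Nnat, an imprinted gene of the developing brain, stood between them at 8145 ± 611. Actb and Actg1, the cytoplasmic actins, were at 5637 ± 312 and 3612 ± 21.4, the actin-binding Tmsb10 and Tmsb4x at 4289 ± 133 and 3919 ± 294, and the beta-tubulin Tubb2a at 2968 ± 288. Globin RNA of red blood cells was among the highest, with Hba-a2 at 5233 ± 560 and Hbb-bs at 3111 ± 148. The other genes of the 15 highest were Ftl1 (iron storage, 4531 ± 118), Ubb (ubiquitin, 3976 ± 30.3), Ppia (a protein folding enzyme, 3335 ± 24.6), Hspa8 (a chaperone, 2861 ± 125) and Rtn1 (a reticulon of neurons, 2789 ± 125).

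Tuba1a (ENSMUSG00000072235.5) lies on chromosome 15 from 98949837 to 98953703 of GRCm38, and Nnat (ENSMUSG00000067786.12) on chromosome 2 from 157560078 to 157562522. At a TPM of at least 1 in both libraries 15223 genes were detected, of which 13333 were protein-coding, 441 processed pseudogenes, 361 antisense genes and 277 long intergenic non-coding RNA genes. At least 10 TPM was reached by 9225 genes, at least 100 by 1744 and at least 1000 by 82. The 100 highest genes took 26.6% ± 0.470 of all TPM, and protein-coding genes 89.3% ± 0.306. The 7 globin genes of the red cell list together took 1.26% ± 0.0965.

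RNA from outside the protein-coding nuclear genes was led by Rn7s1 and Rn7s2, copies of the RNA of the signal recognition particle, at 12305 ± 441 and 12305 ± 442. Every 31-base word of Rn7s1 also occurs in Rn7s2, so the split between them is not resolved, and together they took 2.58% ± 0.0593 of TPM. Of the same class, the transcription regulator Rn7sk was at 247 ± 7.09, while Terc, the telomerase RNA, stayed below 1 in both libraries. The list of structured RNAs had a median of 2.68 ± 0.679. Among long non-coding RNAs, Malat1 of nuclear speckles was at 5763 ± 762, the imprinted Meg3 at 1896 ± 74.5 and Snhg11 at 561 ± 51.3, with a list median of 23.7 ± 0.283. Replication-dependent histone genes, whose mRNA mostly lacks a poly(A) tail, had a median of 2.96 ± 1.37. Hist1h4d was at 72.8 ± 12.7, Hist1h2ae at 17.2 ± 4.89 and Hist1h1e at 7.90 ± 1.84. Hist1h2bf, Hist1h3c, Hist2h2ac and Hist2h3c1 were below 1 in both libraries. The 15 mitochondrial genes took 3.61% ± 0.172 of TPM, with mt-Atp6 at 8283 ± 415, mt-Atp8 at 6421 ± 438 and mt-Cytb, a subunit of respiratory complex III, at 3553 ± 42.0; their list median was 1430.2 ± 117. As a share of expected counts the mitochondrial part was 1.59%, and 4 pseudogenes on chromosome 1 that carry mitochondrial sequence took a further 1.70% ± 0.00420 of TPM. Among these, Gm28437 was at 9338 ± 214 and Gm28661 at 3020 ± 214. All their 31-base words also occur in mitochondrial genes, so the split of reads is not resolved, nor is the level of the mitochondrial genes that share this sequence. In replicate 1 the credibility interval of TPM was wide for mt-Atp6 (5836 to 8981). It was narrow for mt-Atp8 (6414 to 6638) and mt-Cytb (3390 to 3442). With posterior mean TPM the median of the mitochondrial list was 1987.4. The reference genes Actb and Ppia belonged to a list with a median of 919.8 ± 37.6.

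The next comparison asks which regional identities the dissected tissue carried. Otx2, a homeobox gene of forebrain and midbrain, was at 60.4 ± 5.76, Meis2, a homeobox gene of the tectum, at 55.9 ± 4.03, and Tfap2d, a transcription factor of the dorsal midbrain, at 46.2 ± 3.08. Of the genes of hindbrain identity, Hoxa2, Hoxa3, Hoxb2, Hoxb3, Hoxb4 and Hoxd3 were below 1 in both libraries, as were Atoh1, Egr2 and Ptf1a of the rhombic lip, rhombomeres and cerebellum, and Hoxb4 had no count. In the same list 3 of 12 members were detected, Gbx2 and Barhl1 among them. The low values speak for the named genes only and do not exclude tissue from every part of the hindbrain. In the list of the neighbouring diencephalon 4 of 10 members reached 10 TPM in both libraries, with Tcf7l2, a Wnt effector of the thalamus and pretectum, at 793 ± 159, Lhx9 at 118 ± 17.9 and the thalamic Gbx2 at 39.0 ± 19.9.

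Otx2 (ENSMUSG00000021848.11) lies on chromosome 14 from 48657677 to 48673819, and Tcf7l2 (ENSMUSG00000024985.14) on chromosome 19 from 55741820 to 55933654. The list of midbrain territory had a median of 3.87 ± 0.240 with 10 of 13 members detected. En1, a gene of the midbrain-hindbrain boundary and dopamine neurons, was at 5.67 ± 0.955, and En2 and Lmx1b were below 1 in both libraries. The diencephalon list had a median of 6.39 ± 0.332, at percentile 52.8 of random lists, with Rax of the hypothalamus below 1. The forebrain list had a median of 7.53 ± 2.35. Dlx1, of GABA neuron lineages in telencephalon and prethalamus, was at 36.56 ± 14.5, Lhx2 at 34.2 ± 4.59 and Six3 at 18.2 ± 3.20. The list of hindbrain and cerebellum had a median of 0.140 ± 0.0707 and 3 of 12 members detected, among them Gbx2 and Barhl1 (27.0 ± 3.54). The list of muscle, cartilage, skin, retina and pituitary genes had a median of 0.133 ± 0.0460. Col2a1 of cartilage was at 24.1 ± 7.57 and Acta1 of muscle at 8.18 ± 0.785. The genes Myod1, Myh3, Acan, Krt5, Krt14, Crx, Pou1f1 and Prl were below 1 in both libraries. For En2 against Hoxb3 no ratio was formed, since Hoxb3 had 2.86 counts in replicate 1 and 0 in replicate 2.

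**Figure D1:**
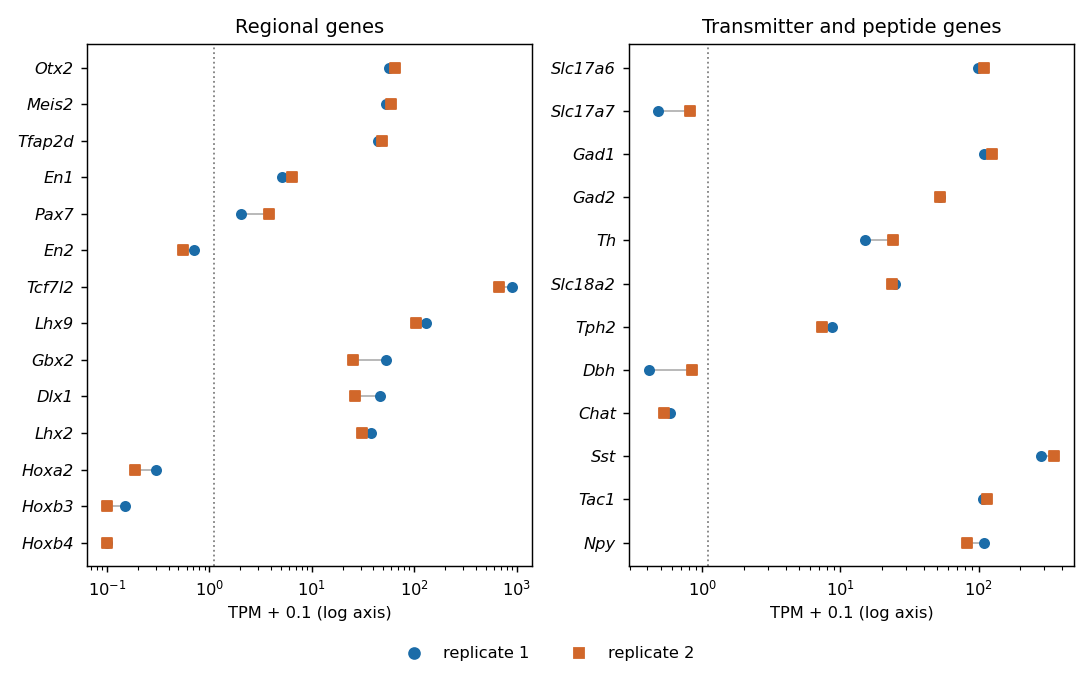
Each panel shows TPM with 0.1 added, on a logarithmic axis, in replicate 1 (circles) and replicate 2 (squares), for regional genes on the left and for transmitter and peptide genes on the right; the dotted line marks 1 TPM. Otx2, Meis2 and Tcf7l2 lie far to the right of the Hox genes, and Slc17a6 and Gad1 lie side by side near 104 and 117 TPM.

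Transmitter genes address which kinds of neurons the midbrain held at this stage. The glutamate transporter gene Slc17a6, of subcortical excitatory neurons, was at 104 ± 6.93 and Gad1, the main GABA-synthesising enzyme, at 117 ± 10.4, a log2 ratio of -0.16 ± 0.0323. Slc17a7, the transporter gene of cortical excitatory neurons, was at 0.550 ± 0.240, 199-fold below Slc17a6 (log2 7.64 ± 0.556). Th, the rate-limiting enzyme of dopamine synthesis, was at 19.5 ± 6.30, 2.41-fold above Tph2 of serotonin neurons (log2 1.27 ± 0.655) and 39.7-fold above Dbh of noradrenaline neurons (log2 5.31 ± 0.413). The neuropeptide gene Sst, for somatostatin, was higher than any of these at 317 ± 50.1.

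The GABA list had a median of 21.7 ± 1.82 with all 12 members detected, among them Gata3 (74.3 ± 4.07), a selector of midbrain GABA neurons, and Gad2 (52.6 ± 0.332), which Gad1 exceeded 2.22-fold. The glutamate list had a median of 18.03 ± 2.57; Lhx9 and Pou4f1 (58.1 ± 7.95), transcription factors of dorsal excitatory neurons, were its other high members. In the dopamine list (median 5.81 ± 1.40) the highest were Dlk1 (49.0 ± 9.60), Nr4a2 (27.9 ± 8.89), the receptor that specifies dopamine neurons, and the vesicle transporter Slc18a2 (24.2 ± 0.940), and 5 of 16 members reached 10 TPM in both libraries. The serotonin list had a median of 5.32 ± 0.491, with Tph2 at 7.90 ± 0.990 and the transporter Slc6a4 at 7.83 ± 1.75. The cholinergic and motor list had a median of 1.46 ± 0.460, with Ache at 47.2 ± 11.1, Isl1 at 30.8 ± 13.4 and Slc18a3 at 2.63 ± 0.509, while Chat, Phox2a and Mnx1 were below 1 in both libraries. In the noradrenaline list (median 0.535 ± 0.304) Dbh, Slc6a2 and Phox2a were below 1 in both libraries and Pnmt was at 1.32 ± 0.127. The peptide list had a median of 14.2 ± 0.474. Tac1, the substance P precursor, was at 111 ± 5.53 and Npy at 96.1 ± 20.0, and Tac2 and Vip were below 1 in both libraries.

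These ratios compare TPM, which is corrected for transcript length. Ratios of expected counts, which are not, turned Slc17a6 against Gad1 to log2 0.37, and moved Xist against Ddx3y from 0.24 ± 0.485 (-0.11 in replicate 1 and 0.58 in replicate 2) to 2.5, Snap25 against Mki67 to 3.54, Pdgfra against Mbp to -0.08 and Grin2b against Grin2a to 4.52; with posterior mean TPM Th against Dbh was 4.34.

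Stage and cell type lists address how far neurons and glia had matured. Genes of young neurons were far above those of dividing cells: Tubb3, the tubulin of new neurons, was at 1779.8 ± 50.9, Gap43 of growing axons at 1584 ± 110 and Stmn2 at 1141 ± 35.8, with a list median of 263 ± 26.4. Tubb3 stood 137-fold above the progenitor factor Sox2 (log2 7.10 ± 0.444), and Snap25, of the synaptic vesicle fusion machinery, 60.2-fold above the proliferation marker Mki67 (log2 5.91 ± 0.814). Glial genes were split, with Fabp7 of radial glia at 1409 ± 220 and Apoe of astrocytes at 431 ± 191, while Gfap, the filament of mature astrocytes, was at 0.625 ± 0.559. Slc1a3, a glutamate transporter of radial glia and astrocytes, was 213-fold above Gfap (log2 7.73 ± 1.24), a value that rests on 11 and 56 counts of Gfap: it was 8.61 in replicate 1, 6.86 in replicate 2 and 7.03 with posterior mean TPM.

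In the progenitor list (median 37.1 ± 1.72) Vim and Id4 followed Fabp7 at 285 ± 36.8 and 235 ± 64.7. The cell cycle list had a median of 20.5 ± 4.65, with the replication genes Pcna (76.7 ± 4.58) and Rrm2 (33.1 ± 2.62) and the kinase gene Cdk1 (33.9 ± 10.6) highest. The neurogenic list had a median of 11.4 ± 3.80, led by Gadd45g (37.7 ± 1.14), Btg2 (26.1 ± 4.81) and the Notch ligand Dll1 (15.2 ± 0.615). Genes of mature synapses and channels had a median of 43.7 ± 0.212, with Vamp2 (324 ± 58.0) and Gria2 (209 ± 10.7) among the highest and the potassium channel Kcna1 below 1. The NMDA receptor subunit gene Grin2b, typical of immature synapses, was 6.49-fold above Grin2a (log2 2.70 ± 0.148). The astrocyte list had a median of 62.3 ± 12.2, with Sparcl1 at 149 ± 39.0 and Glul, glutamine synthetase, at 126 ± 7.25. In the oligodendrocyte precursor list (median 7.2 ± 0.156) Olig1 was at 94.6 ± 21.1, Pdgfra at 10.9 ± 1.46 and Olig2 at 8.0 ± 0.813. The myelin list had a median of 3.86 ± 0.120. Cnp was at 43.8 ± 6.29, Cldn11 at 33.1 ± 2.73 and Mbp at 18.5 ± 1.16, 1.71-fold above Pdgfra, while Mobp, Myrf and Opalin were below 1 in both libraries. The Mbp value sums all its transcripts, and 74.3% ± 0.438 of it was Mbp-205, a form of 4 exons. Which forms encode the protein of myelin was not tested, so the ratio to Pdgfra does not set myelin against precursors.

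Among cells of other origin, the microglia list had a median of 6.04 ± 0.159, with the complement genes C1qb at 29.4 ± 6.50 and C1qa at 20.6 ± 1.82 and Tyrobp at 16.1 ± 4.56, and Ptprc below 1. The endothelial list had a median of 18.2 ± 0.651, led by Cldn5 of tight junctions (87.5 ± 1.34), the glucose transporter Slc2a1 (80.2 ± 1.48) and Esam (34.0 ± 2.23). The list of pericytes, fibroblasts and meninges had a median of 13.6 ± 0.590, led by the collagen genes Col3a1 (99.5 ± 7.16), Col1a1 (59.8 ± 15.2) and Col1a2 (59.5 ± 8.87), with Foxd1 below 1. The red cell list had a median of 25.2 ± 5.09. Hba-a1 was at 2018 ± 191, and the adult Hbb-bs stood 324-fold above the embryonic Hbb-y (log2 8.34 ± 1.29; 7.43 in replicate 1 and 9.25 in replicate 2), with the embryonic Hbb-bh1 below 1. The choroid plexus and ependyma list had a median of 8.86 ± 0.499, with Ttr, the thyroxine carrier of the choroid plexus, at 376 ± 48.9, Folr1 at 20.1 ± 0.0707 and Kl below 1. The handling lists had medians of 3.32 ± 0.170 for immediate early and stress genes (Jun 43.4 ± 2.34, Dusp1 28.5 ± 1.16, Hspa1a 13.7 ± 3.37, Fosb and Hspa1b below 1) and 60.2 ± 0.488 for genes induced by low oxygen (Ldha 543 ± 57.4, Pgk1 215 ± 11.6, Bnip3 91.6 ± 3.01). In all, 18 of the 34 lists had a median of at least 10 TPM.

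Transcript values address which transcript forms of neuronal genes the midbrain used. Snap25-201 gave 88.0% ± 2.503 of the TPM of Snap25, and Ncam1-204 74.0% ± 0.912 of Ncam1, a cell adhesion gene. For Mapt, the gene of tau, Mapt-205 gave 46.4% ± 1.22 and Mapt-204 34.1% ± 0.636. For Gad1 the largest part, 57.7% ± 3.57, was a transcript annotated as non-coding, Gad1-206, ahead of the coding Gad1-201 with 35.0% ± 2.11. For Gria2, an AMPA receptor subunit gene, the annotated retained-intron form Gria2-206 gave 42.2% ± 1.61 and the coding Gria2-202 37.0% ± 2.06.

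The leading forms of the other described genes were Map2-201 (41.0% ± 1.90), Dcx-203 (44.3% ± 3.14), Ank3-231 (25.1% ± 0.318), Clta-204 (74.4% ± 0.530), Cdc42-201 (58.0% ± 0.721), Tpm1-209 (38.3% ± 4.16) and Mbp-205 (74.3% ± 0.438). All TPM of Th was assigned to Th-201. Of the splicing regulator genes, Ptbp1 was split between Ptbp1-202 (38.0% ± 2.06) and Ptbp1-216 (37.1% ± 2.43), with Ptbp1-216 the larger in replicate 1 and Ptbp1-202 in replicate 2, while Ptbp2, the neuronal relative, and En2 had 1 annotated transcript each. Transcript models of Dlg4, Slc17a6 and Pkm differed in length between the annotation releases and are not described. Over 8248 genes at 5 TPM or more with at least 2 transcripts, the same transcript was highest in both libraries in 7641 (92.6%), its median share was 67.7% ± 0.742, and in 1697 genes (20.6%) it held at least 90% in both.

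The last comparison asks how far the pools differed. Astrocyte genes were higher in replicate 2, by a median of 1.65-fold (log2 0.72, replicate 2 minus replicate 1) with 9 of 10 members higher. These included Apoe, a lipid carrier of astrocytes, at 296 and 566 TPM in replicates 1 and 2, Aldoc at 73.7 and 129, and Aqp4, the water channel of astrocyte endfeet, at 2.67 and 6.96. Cell cycle genes were lower in replicate 2 in all 12 members, with a median 1.31-fold higher in replicate 1 (log2 -0.39). Cdk1 was at 41.5 and 26.4. Y-linked genes were lower in replicate 2, with Eif2s3y at 50.2 and 25.6 and Ddx3y at 18.2 and 13.0, while Xist, the RNA of X inactivation, was at 16.9 and 19.4. Genes of the diencephalon and forebrain were lower in replicate 2, by medians of log2 -0.28 (8 of 10 members lower) and -0.26 (8 of 12 lower), with Gbx2 at 53.1 and 25.0 and Dlx1 at 46.8 and 26.3.

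The medians of 17 of the 34 lists lay outside the central 95% of 10000 random lists of the same size and expression, which is a description and not a test. Higher in replicate 2, besides the astrocyte list, were the noradrenaline list (log2 1.09, 4 of 4 members, all of low level), the cholinergic and motor list (0.41, 4 of 6), oligodendrocyte precursors (0.30, 6 of 7), the serotonin list (0.25, 4 of 6), neuropeptides (0.22, 11 of 15), mature synapses (0.17, 11 of 14) and genes induced by low oxygen (0.15, 7 of 8). Lower in replicate 2, besides the cell cycle, diencephalon and forebrain lists, were the sex-linked list (log2 -0.67, 4 of 6 members lower), which had a level of 12.8 ± 1.95, hindbrain and cerebellum (-0.51, 4 of 5), histones (-0.50, 6 of 8), red cells (-0.19, 8 of 9), the neurogenic list (-0.17, 9 of 10) and mitochondrial genes (-0.11, 11 of 15). Within the neurogenic list Neurog2, a proneural factor, was at 14.3 and 4.34. Inside the range were the lists of dopamine (0.14), GABA (0.08) and glutamate neurons (0.09), progenitors (-0.06), young neurons (0.03), myelin (0.10), microglia (0.16), endothelium (-0.03), pericytes and meninges (-0.06), choroid plexus (-0.06), midbrain territory (0.12), other tissues (-0.19), stress genes (-0.01), structured RNAs (-0.05), long non-coding RNAs (-0.05), reference genes (0.05) and the genes described by transcript (0.05), whose median level was 155.6 ± 2.12. With TPM ratios the serotonin (0.20) and neurogenic (-0.13) lists lay inside the range and midbrain territory (0.15) outside, and with members at a mean count of at least 50 the dopamine (0.33) and GABA (0.10) lists lay outside.

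**Figure D2:**
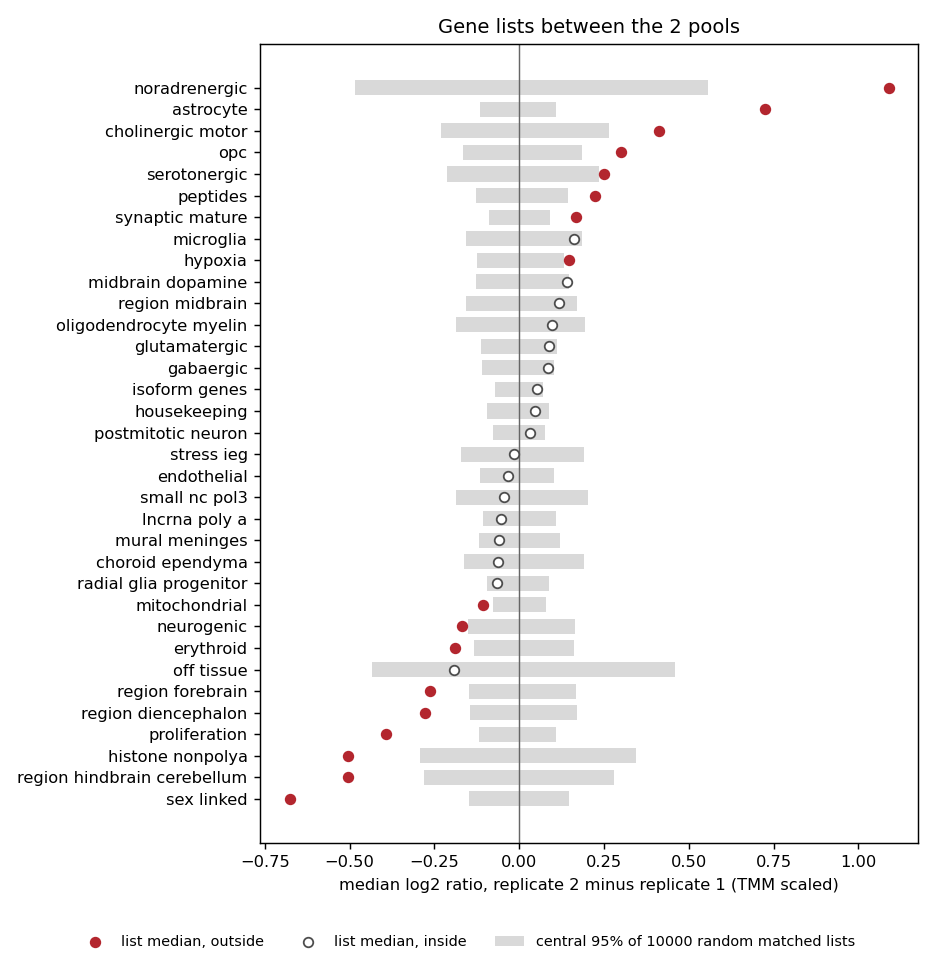
Points show the median log2 ratio of each gene list, replicate 2 minus replicate 1, relative to the scale set by all genes, and bars the central 95% of 10000 random lists of matched size and expression. The astrocyte list lies at 0.72 and the cell cycle list (proliferation) at -0.39, each outside its bar; on the spike-in scale every list would lie lower, by log2 -0.59 for the median gene (opc, oligodendrocyte precursors; ieg, immediate early genes; pol3, structured RNAs).

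At least a 2-fold difference was found in 92 of 14412 genes with a mean expected count of 50 or more, 50 higher in replicate 2 and 42 in replicate 1. Higher in replicate 2 were Mmp13, a collagenase, with 2 and 175 counts (76.6-fold as the scaled ratio of these counts with nothing added, 95% counting interval 20.9 to 637; 61.4-fold with 0.5 added, as for the genes that follow), Ibsp, bone sialoprotein (9.10-fold), Oxt, the oxytocin precursor (15.3-fold, 0.790 and 12.7 TPM), Nanp, an enzyme of sialic acid synthesis (10.5-fold), and Agt, angiotensinogen (6.55-fold). Higher in replicate 1 were Rspo3, an activator of Wnt signalling (5.63-fold, 21.3 and 3.70 TPM), Pmch, the precursor of melanin-concentrating hormone (4.69-fold, 51.1 and 10.7 TPM), Robo3, a receptor of commissural axons (4.20-fold), Kcng4, a potassium channel subunit (6.17-fold), Gng8, a G protein subunit (3.75-fold), and Hbb-y (3.67-fold). Mmp13 and Ibsp are genes of bone, and the list of other tissues holds no bone gene. Processed pseudogenes made up the rest of the largest ratios. Gm10233 and Gm4294 had 0 counts in replicate 1 and were at least 95.2-fold and 86.7-fold higher in replicate 2, and Gm13394 was 4.98-fold higher there. Gm15459, with 0 counts in replicate 2, was 48.2-fold higher in replicate 1 against that floor, and Gm10171 was 12.4-fold higher there. The credibility intervals of TPM overlapped between the libraries for Gm10233, Gm4294, Gm13394 and Gm15459, but not for Gm10171. For Gm4294 they were 0.0101 to 284 in replicate 1 and 7.92 to 265 in replicate 2. The floor covers counting error only and not the division of shared reads, so the ratios of the overlapping pseudogenes are no lower bounds. Gh, the growth hormone gene of the pituitary, had 0 and 17 counts, at least 4.96-fold higher in replicate 2.

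**Figure D3:**
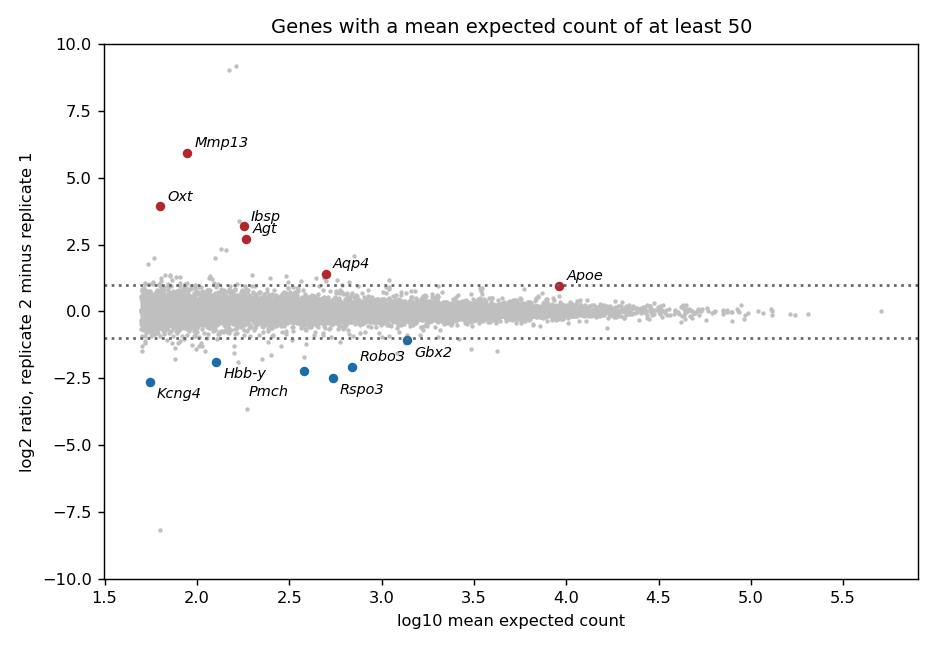
Each grey point is a gene with a mean expected count of at least 50, placed by the logarithm of that count and by its log2 ratio, replicate 2 minus replicate 1, with 0.5 added to each count; dotted lines mark 2-fold. Coloured points are named genes, with Apoe just under the upper line, Mmp13, Ibsp and Oxt above it, and Rspo3, Pmch and Robo3 below the lower one.

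Rspo3 (ENSMUSG00000019880.9) lies on chromosome 10 from 29452416 to 29535867, Apoe (ENSMUSG00000002985.11) on chromosome 7 from 19696109 to 19699188, and Gbx2 (ENSMUSG00000034486.8) on chromosome 1 from 89927956 to 89931179. Across 15807 genes with a mean TPM of at least 1, log2(TPM + 1) of the libraries gave Pearson r = 0.985 and a Spearman correlation of 0.986. Genes are not independent replicates. The biological coefficient of variation was 9.82% over 17788 genes, and 81.4% of genes with a mean count of at least 50 lay within 1.2-fold. Spike-in RNA took 1.49% of expected counts in replicate 1 (95% Wilson interval 1.489 to 1.497) and 2.23% in replicate 2 (2.228 to 2.238), a mean of 1.86% ± 0.523, so that endogenous RNA per spike-in was 1.51-fold higher in replicate 1. The labels do not give the amount of spike-in added to each library. A different amount added would give the same ratio, so it is no measure of RNA content. With spike-ins as the scale the median gene was lower in replicate 2 (log2 -0.59), 498 genes differed by 2-fold, 13 higher in replicate 2 and 485 in replicate 1, and the coefficient of variation was 30.9%. Of the lists named as higher in replicate 2 only the astrocyte and noradrenaline lists stayed above 0 on that scale. All ratios between pools given here are relative to the median gene. At a mean count of at least 10 the number at 2-fold was 495 and at 200 it was 29.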

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

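A signal appeared in a part of the gene tables that no comparison uses, the 26248 entries named by a number only. They held 12 expected counts in replicate 1 and 12 in replicate 2, above the 3 counts that a count of 0 allows, with no control samples to compare. Counts fell on 10 of the entries, and 1 of them, of 255 bases, had counts in both libraries, 7 and 8.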

How the results depend on the processing

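The alternative that counts 4 pseudogenes as mitochondrial was chosen after seeing the data; the others were set beforehand. The share of the 100 highest genes was 17.8% of expected counts, 25.0% of TPM over nuclear genes and 23.5% over protein-coding genes. The mitochondrial share was 1.59% of expected counts, 3.18% without ribosomal RNA genes and 5.31% with the pseudogenes. Expected counts give weight to long genes, and the other settings alter the genes summed. The spike-in share was 4.60% of TPM. The correlation was 0.960 with a pseudocount of 0.1, 0.994 without a filter, 0.988 at a mean TPM of 10 or more, 0.987 for FPKM and 0.957 for transcripts; the cause was not tested. Spike-in scaling gave a coefficient of variation of 30.9% and 498 genes at 2-fold, since it moves all genes by one factor; for the same reason it left the list percentiles as they were. Genes at 2-fold numbered 495 at a mean count of at least 10 and 29 at 200, where 17773 and 11767 genes were compared. Slc17a6 against Gad1 reversed to log2 0.37 with expected counts, which are not corrected for length. The same main transcript was found in 94.4% of genes at 20 TPM and 90.7% at 1 TPM, and its median share was 68.6% at 1 TPM and 64.4% with posterior means; the cause was not tested. Leaving out each library in turn gave 15759 to 15820 detected genes, 26.2 to 26.9% for the 100 highest, 3.48 to 3.73% mitochondrial, 1.49 to 2.23% spike-in, 17 to 18 lists at 10 TPM and a median transcript share of 67.2 to 68.2%. Between 16 and 17 lists lay outside the random range in the alternatives. At a count of 50 the noradrenaline, hindbrain and other-tissue lists had fewer than 4 members and could not be compared, although the noradrenaline and hindbrain lists lay outside at 10. Of single lists, 94 values kept their direction and side. Of these values, 34 came from spike-in scaling with the shift of all genes removed, which leaves the list medians unchanged by construction and so tests nothing. Dopamine and GABA moved outside at a count of 50 and midbrain territory with TPM, and serotonin and neurogenic lists moved inside with TPM. Depth limits the noradrenaline list, whose members have few counts and whose random range was -0.48 to 0.56.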

Other observations

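The tests of Xist, of adult globins and of counting noise, the age comparisons without glial and cell division genes, the thalamus list without Dlx6, the comparison of 31-base words and the choice of the single genes in this paragraph were made only after the result was seen. The genes were picked for their values, so they stand for no group. Spp1, osteopontin, was at 10.2 and 41.6 TPM in replicates 1 and 2 (4.17-fold higher in replicate 2). Of other bone genes besides Mmp13 and Ibsp, Bglap and Bglap2 had 0 counts in replicate 1 and 5 and 9 in replicate 2. Col1a1, Alpl, Runx2 and Sp7 were 1.48-fold, 1.35-fold, 1.72-fold and 1.53-fold higher in replicate 2. None of the bone genes looked at was lower there, and whether bone tissue entered that pool was not tested. Zic4, a zinc finger factor of the dorsal neural tube, was at 129 and 46.3 TPM (2.76-fold higher in replicate 1), Zic1 and Zic5 were 2.26-fold and 2.94-fold higher there, and Gpr151, a receptor of habenula neurons, 2.94-fold. Avp, the vasopressin precursor, was at 64.3 and 64.9 TPM.

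Second lists gave further cell types. Of 16 other astrocyte genes 15 were higher in replicate 2, with a median log2 ratio of 0.53; Hepacam, an adhesion molecule of astrocytes, was at 11.7 and 21.4 TPM and Bcan, a proteoglycan of the extracellular matrix, at 43.5 and 80.7. Of 12 hypothalamus genes 9 were lower in replicate 2, with a median of -0.84. The other 3 were higher, Oxt by log2 3.93. Of the lower genes Nkx2-4, Nr5a1, Hmx2 and Hmx3 had a mean below 1 TPM, with 18 and 5 counts for Hmx3, so the median rests partly on genes of low level. Of 11 measured ventral midbrain genes 7 were higher in replicate 2, with a median of 0.18, above 98.98% of random lists; without En1, whose value had been seen, it was 0.13, inside the central range. Ftl1 also holds the annotated micro-RNA gene Gm22133, whose 31-base words all occur in Ftl1. Of the pseudogenes that carry mitochondrial sequence, Gm28437, Gm28661 and Gm10925 share 100% of their words with mitochondrial genes and Gm29216 97.2%.

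The 4 Y-linked genes were lower in replicate 2, with log2 ratios from -0.56 to -0.94 relative to the median gene. Reads shared with X-linked relatives were tested by the credibility intervals of TPM, which widen where reads are shared. Of the 4 genes, 0 had intervals that overlapped between the libraries. That argues against uncertain division of shared reads as the cause, while reads wrongly assigned alike in both libraries were not tested. A different share of male embryos in the pools is a candidate explanation, and Xist moved the other way with a log2 ratio of 0.27 on that scale and intervals of TPM apart. X-linked genes that escape inactivation had a median of -0.03, with 3 of 6 higher. The labels give mixed sex for both pools and no counts by sex, so this stays a hypothesis.

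Astrocyte genes were higher and cell cycle genes lower in replicate 2, with list medians 1.12 apart on the log2 scale. After removal of the trend on GC content and gene length, which held 3.10% of the variance, they were 1.07 apart, so that trend is not the whole cause. The 4 adult globin genes had a median of -0.17, which argues against blood left in different amounts as the source of a difference of this size. Blood genes still differed: the red cell list was lower in replicate 2 (-0.19, 8 of 9 members), outside the range of random lists. The embryonic globin genes Hbb-y and Hba-x were 3.67-fold and 3.43-fold higher in replicate 1. A later average stage of the pool of replicate 2 could account for the astrocyte and cell cycle pattern. Genes rising with age exceeded genes falling with age by 0.76, against -0.11 to 0.11 for random pairs of lists. The difference was 0.69 without glial genes, and 0.60 without glial genes and Ccnd1, Hmgb2 and Ezh2, which are tied to cell division. The lists overlap the pattern in kind, and the falling genes Sox4 (0.03), Dpysl3 (0.01), Crmp1 (0.06) and Tubb2b (0.10), of young neurons, were not lower. A difference in the parts of the midbrain dissected, or in the mixture of cells, could do the same and stays open, since the design has 1 pool on each side.

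Dlx1, Dlx2, Dlx5 and Gbx2 were lower in replicate 2, with log2 ratios from -0.89 to -1.28. Of the 4, 0 lay within 2 counting standard errors of no difference, and these errors were 0.06 to 0.13 on the log2 scale. The genes were picked because they differed, so this count was largely fixed by the choice. It describes the size of the differences and is no test of counting noise. More thalamus and prethalamus tissue in the pool of replicate 1 is a candidate explanation: 14 genes of these regions had a median of -0.18 (percentile 0.02 of random lists), -0.20 without Cck, whose value had been seen, and -0.15 (percentile 0.13) without Dlx6, itself a Dlx gene. That median is far smaller than the differences of the 4 genes, and 5 of the 14 were higher in replicate 2, among them Cck (0.64), Rorb (0.33) and Lef1 (0.25), so the list leaves most of their size unaccounted for. Dissection and stage stay open together, since with a single pool on each side neither could be tested apart.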
